A study of Mus musculus with 11 samples.

How the data were processed

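Bone marrow of 4 female C57BL/6NTac mice was depleted of lineage-positive cells and sorted by flow cytometry, per the labels' protocols. LT-HSCs were gated as CD150-positive, CD48-negative cells with high Sca-1 and c-Kit and divided by EMCN, and GMPs were sorted beside them. RNA of 3000 to 5000 sorted LT-HSCs per sample, per the series' design text, was made into libraries with a SMARTer stranded total RNA kit for picogram input and sequenced in read pairs on a NextSeq 500. The molecule is given as polyA RNA in the labels, which the kit's protocol does not select for. The submitters removed 1 EMCN- library for poor quality, which left 4 EMCN+ LT-HSC, 3 EMCN- LT-HSC and 4 GMP libraries. The mouse number in the labels gave the replicate and the pairing, with EMCN+ and EMCN- libraries of mice 1, 2 and 4 as 3 complete LT-HSC pairs.

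The deposited values are estimated counts per gene for 54347 genes and 11 libraries, made with cutadapt and Salmon per the submitters' processing notes. Tool versions, the genome build and annotation, the step from transcripts to genes and the rounding were not given in the sources used here, and the values are whole numbers. As a safeguard the estimated counts were rounded to whole numbers before each fit. Gene symbols, biotypes, transcript lengths, GC content and coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier. Of the 54347 identifiers 54094 matched without and 53307 with the version number, and 27109 had a symbol in the count table. Counts were 0 in all libraries for 21223 genes.

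Totals per library ranged from 3.63 to 11.1 M estimated counts. A single count was worth 0.0697 to 0.235 CPM with TMM factors, and 3 counts, the upper limit that a count of 0 allows, were worth 0.209 to 0.705 CPM. The kit's reads were counted without molecular identifiers, so floors and intervals cover counting error only. Replicates of a group differed beyond sampling, with a chi-square per degree of freedom from 8.41 to 34.9 over all pairs of libraries.

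Genes were filtered by group with filterByExpr at a minimum count of 10, which left 14915 genes with 99.7% of the counts. All 11 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM factors, robust quasi-likelihood dispersions and no mouse block, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were EMCN+ versus EMCN- LT-HSCs, LT-HSCs versus GMPs with the 7 LT-HSC libraries weighted equally, and each LT-HSC fraction versus GMPs. Log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance. Of 27 lists 25 had at least 5 tested members. They hold cell surface, stem cell, quiescence, cell cycle, biosynthesis, metabolic, adhesion, lineage, response and other-cell-type genes, and some genes belong to more than one list. The 2 sets of 200 genes, the exact permutation test of their score and these tests, lists and named-gene rules were fixed before the data were examined.

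Named genes were the surface genes of the sort, up to 10 genes per direction with the largest change among those called, and up to 4 called members of each list, or up to 2 with the smallest p where none was called. The 10 per direction had a mean of at least 5 CPM, every library of one group above every library of the other and a symbol that is not a predicted model. For 8 genes, Emcn, Cd48, Cd34, Mecom, Vwf, Runx3, Plac8 and Itga2b, values against GMPs in each fraction were chosen after the EMCN+ versus EMCN- values were seen. Not every member allowed by the rule was named, and some genes are not reported here. A gene with 0 counts in a group is given as a bound against 3 counts over the group, and one with 1 to 3 counts as a ratio with an exact 95% counting interval.

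Alternatives planned before the data were examined were RLE and upper-quartile factors, no low-count filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust dispersion, mouse as a block, the 7 LT-HSC libraries alone, the 6 libraries of complete pairs with mouse as a block, an unweighted LT-HSC mean, sets of 100 and 500 genes, and each library left out in turn. Alternatives added later were total-count scaling, protein-coding genes alone, the 8 libraries of mice 2 to 4, a correction for length and GC content with and without a mouse block, libraries thinned to the smallest total, and an estimated correlation with a mouse block. Same-mouse pairs of LT-HSC libraries had a mean correlation of 0.198 between their deviations from the group means (0.165 to 0.223, 3 pairs). For 9 pairs from different mice the mean was -0.0657 (-0.246 to 0.190), so the ranges overlap. Deviations cancel over a group, so both means are tied and the second is no independent reference.

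The test was checked on simulated data, in which 200 of 14915 genes were changed, 67 by 1.5-fold, 67 by 2-fold and 66 by 4-fold. For EMCN+ versus EMCN- it recovered 23.9%, 68.7% and 95.5% of them with 9 false calls, and for LT-HSCs versus GMPs 37.3%, 74.6% and 98.5% with 7. For EMCN+ LT-HSCs versus GMPs it recovered 23.9%, 76.1% and 100% with 6 false calls, and for EMCN- LT-HSCs versus GMPs 17.9%, 79.1% and 90.9% with 7. Of 100 random gene sets camera called 2 at the preset correlation and 1 with an estimated correlation. The changed genes were picked among those with a mean of at least 5 CPM over all 11 libraries. The recovery of genes below that level was not checked, and no mouse effect was simulated. The simulated genes were drawn independently, so this check does not cover lists whose members move together. The histone list, for example, had an estimated correlation of 0.768. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.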

Results

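RNA was sequenced from long-term haematopoietic stem cells (LT-HSCs) sorted from the bone marrow of female C57BL/6NTac mice and divided by the surface protein endomucin (EMCN), a sialomucin known from endothelium. There were 4 libraries of EMCN+ LT-HSCs, 3 of EMCN- LT-HSCs and 4 of granulocyte-monocyte progenitors (GMPs), a more differentiated population. The libraries came from 4 mice, so replicates of a population are separate animals. Mean totals were 7.60 ± 2.77 M (1e6) estimated counts (SD, n = 4) in EMCN+ LT-HSCs, 4.87 ± 1.09 M (n = 3) in EMCN- LT-HSCs and 7.87 ± 1.39 M (n = 4) in GMPs, with single libraries from 3.63 to 11.1 M. Mitochondrial ribosomal RNA took 18.0 ± 4.06%, 18.2 ± 0.762% and 27.6 ± 1.28% of the counts in the same order. The noncoding RNAs Rn7s1, Rn7s2, Rn7sk, Rpph1 and Rmrp together took 2.85 ± 1.09%, 4.85 ± 0.604% and 7.75 ± 0.394%. The first principal component of log2 CPM, counts per M counts, held 73.1% of the variance and separated the GMP libraries from all 7 LT-HSC libraries.

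The comparison of EMCN+ with EMCN- LT-HSCs asked how stem cells that carry endomucin differ from those that do not. In EMCN+ LT-HSCs the imprinted noncoding RNA H19 rose by 3.86 ± 0.52 (SE) on the log2 scale, and the growth factor genes Pdgfc and Igf1 rose by 3.09 ± 0.37 and 2.48 ± 0.34. The transcription factor gene Runx3 fell from 36.9 ± 2.96 CPM (SD, n = 3) to 13.3 ± 0.384 CPM (n = 4), a log2 change of -1.48 ± 0.13. The platelet chemokine gene Pf4 fell from 15.9 ± 4.13 to 2.99 ± 1.30 CPM, a log2 change of -2.38 ± 0.38. Each of these 5 genes moved in the stated direction in 3 of 3 within-mouse pairs. This follows from their selection, which required every library of one fraction to lie above every library of the other, and adds no support. Their edgeR quasi-likelihood adjusted p values were 0.000882 for H19, 0.000257 for Pdgfc, 0.0012 for Igf1, 6.48e-06 for Runx3 and 0.00237 for Pf4. Of 14915 genes tested, 293 (1.96%) differed by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 115 higher and 178 lower in EMCN+ LT-HSCs. Of these, 55 were higher and 36 lower by more than 1 on the log2 scale. Scaling by total counts shifted the median gene by 0.11 and gave 161 higher and 50 lower genes, 76.3% higher against 39.2%. The number of genes fell to 55 without EMCN- replicate 1, 105 without EMCN+ replicate 2, 184 without EMCN+ replicate 4, 194 without EMCN- replicate 2 and 191 without EMCN- replicate 4, and to 90 with mice 2 to 4. It was 374 with mouse as a block, 908 with mouse as a block in the 6 libraries of complete pairs, 451 with DESeq2, 464 with protein-coding genes alone and 529 without a low-count filter.

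H19 (ENSMUSG00000000031.16) lies on chromosome 7 from 142575529 to 142578143 in genome build GRCm38. Pdgfc (ENSMUSG00000028019.9) lies on chromosome 3 from 81036416 to 81214040 and Emcn (ENSMUSG00000054690.17) on the same chromosome from 137341067 to 137432185. Pf4 (ENSMUSG00000029373.7) lies on chromosome 5 from 90772435 to 90773383 and Runx3 (ENSMUSG00000070691.10) on chromosome 4 from 135120652 to 135177990. Other large increases with every EMCN+ library above every EMCN- library were those of Ndnf (2.98 ± 0.46 on the log2 scale), Sult1a1 (2.19 ± 0.31), Smtnl1 (2.18 ± 0.30), Ncam2 (2.15 ± 0.35) and Cyp26b1 (2.68 ± 0.44), the gene of an enzyme that breaks down retinoic acid. Their edgeR adjusted p values ran from 0.00125 for Sult1a1 to 0.00475 for Cyp26b1. Meg3 and Rian, noncoding RNAs of the imprinted Dlk1-Dio3 locus, rose to 10.8 ± 4.10 from 1.36 ± 1.31 CPM and to 17.4 ± 7.46 from 4.19 ± 1.86 CPM, with edgeR adjusted p of 0.0403 and 0.0253. Meg3 lost its call without any one of EMCN- replicates 1 and 4 and EMCN+ replicates 2, 3 and 4 (adjusted p from 0.0643 to 0.165). Rian lost its call without any one of the same libraries other than EMCN+ replicate 3 (adjusted p from 0.0637 to 0.165).

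The other large decreases were those of Synpo2 (-2.05 ± 0.35), Plac8 (-1.74 ± 0.21), the water channel gene Aqp1 (-1.64 ± 0.41), Spns3 (-1.61 ± 0.20), Itga2b (-1.53 ± 0.26), Tuba8 (-1.47 ± 0.29), Dnajc6 (-1.34 ± 0.23) and Plek (-1.32 ± 0.25). Itga2b encodes the platelet integrin CD41 and Plek the platelet protein pleckstrin. Their edgeR adjusted p values ran from 0.000257 for Spns3 to 0.0483 for Aqp1. Without EMCN- replicate 1 the adjusted p was 0.0647 for Synpo2, 0.0524 for Itga2b, 0.132 for Tuba8 and 0.0959 for Plek. Plek also had an adjusted p of 0.136 with mouse as a block in the 6 libraries of complete pairs, 0.0559 with mouse as a block and the length and GC correction in the 7 LT-HSC libraries, 0.0586 with these 7 libraries alone and 0.153 with mice 2 to 4. Itga2b also had an adjusted p of 0.0539 without EMCN+ replicate 2. Aqp1 had an adjusted p of 0.101 with mouse as a block, and it lost its call without any one of 8 libraries, all but EMCN- replicate 2 and GMP replicates 1 and 4 (adjusted p from 0.0635 to 0.275).

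**Figure D1:**
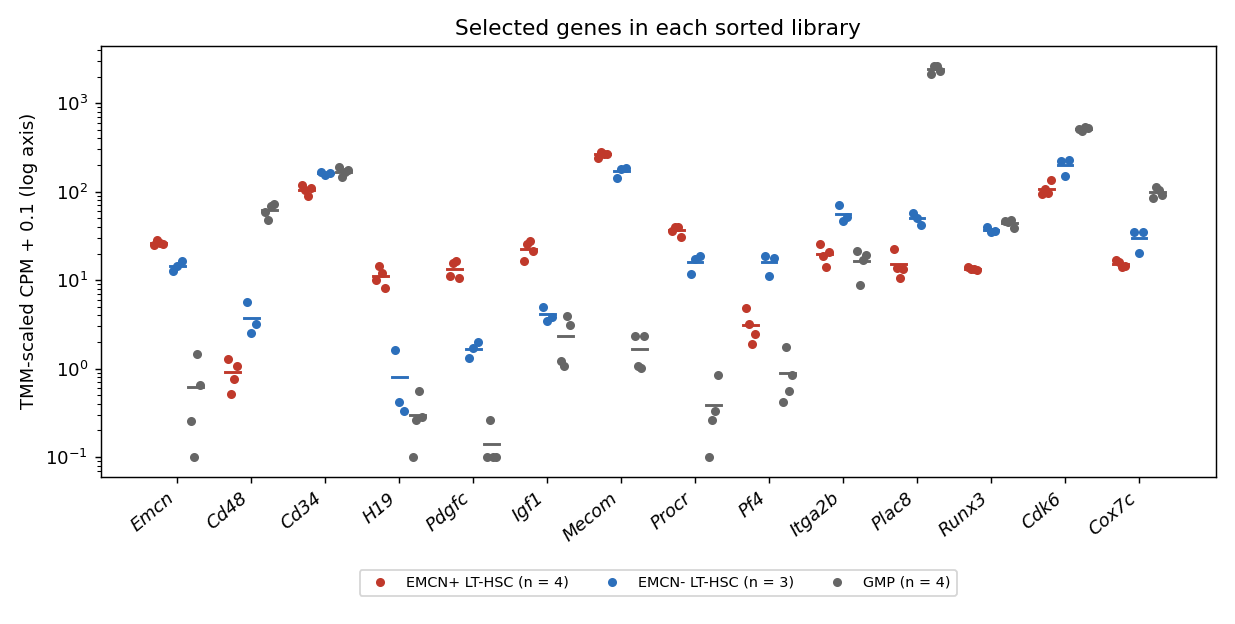
Each point is the level of a gene in 1 library, in CPM plus an offset of 0.1 on a log axis, for EMCN+ LT-HSCs (4 libraries), EMCN- LT-HSCs (3) and GMPs (4), with bars at the group means. H19, Pdgfc and Igf1 lie higher in every EMCN+ than in every EMCN- library, and Runx3, Pf4 and Plac8 lie lower.

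Of 12 surface genes of the sort 10 were tested. Both fractions came from the same gate of CD150, CD48, Sca-1 and c-Kit and were divided by EMCN, and CD34 is not among the antibodies given in the labels. Cd48 fell from 3.66 ± 1.63 CPM in EMCN- to 0.814 ± 0.340 CPM in EMCN+ LT-HSCs, a log2 change of -2.26 ± 0.37 (edgeR adjusted p = 0.00358), with GMPs at 62.1 ± 10.9 CPM. Cd34 fell from 161 ± 7.17 to 106 ± 12.8 CPM, a log2 change of -0.60 ± 0.12 (edgeR adjusted p = 0.00863). Without EMCN- replicate 1 the adjusted p was 0.0596 for Cd48 and 0.0647 for Cd34, and with scaling by total counts it was 0.0912 for Cd34. Cd48 also had 0.0783 with limma-voom and 0.0534 with the 7 LT-HSC libraries alone. Emcn stood at 26.2 ± 1.37 CPM in EMCN+ and 14.4 ± 1.76 CPM in EMCN- LT-HSCs, against 0.521 ± 0.611 CPM in GMPs, and each EMCN+ library lay above each EMCN- library. Its log2 difference of 0.87 ± 0.27 had an edgeR adjusted p of 0.11, and it passed in 10 of 27 alternatives, which ran from an adjusted p of 0.00105 to 0.397. With mouse as a block it passed in the 6 libraries of complete pairs (0.0037) and in the 7 LT-HSC libraries with the length and GC correction (0.00105). It did not pass with mouse as a block in all 11 libraries. The other surface genes did not pass: Ly6a (Sca-1) differed by 0.60 ± 0.32, Slamf1 (CD150) by 0.18 ± 0.21, Kit by 0.01 ± 0.13, Ptprc (CD45) by -0.04 ± 0.10, Itgam by 0.37 ± 0.30, Fcgr2b by -1.55 ± 0.72 and Fcgr3 by -1.14 ± 0.42. This list had 0 higher and 2 lower genes (1 and 2 adjusted over the list alone) and a camera adjusted p of 0.166.

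Of 32 stem cell identity genes 9 rose and 0 fell (14 and 0 adjusted over the list alone), 30 had a positive change and the median was 0.41 on the log2 scale. Mllt3 rose to 237 ± 28.7 from 135 ± 22.6 CPM (edgeR adjusted p = 0.00217). Procr, the gene of the endothelial protein C receptor, rose to 36.3 ± 4.09 CPM (adjusted p = 0.00795), and the transcription factor gene Mecom rose to 265 ± 17.2 from 170 ± 23.6 CPM (adjusted p = 0.0135). The list had a camera adjusted p of 9e-09, and adjusted p = 0.0796 with an estimated correlation. Of 26 quiescence genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.17. They were Gfi1, a repressor of stem cell proliferation (1.45 ± 0.23, edgeR adjusted p = 0.00217), and Cdkn1c, the gene of the cyclin-dependent kinase inhibitor p57 (0.89 ± 0.20, adjusted p = 0.0264). This list had a camera adjusted p of 0.0289, and adjusted p = 0.129 with an estimated correlation. Without EMCN- replicate 1 the adjusted p was 0.0738 for Procr, 0.137 for Mecom and 0.204 for Cdkn1c, and without EMCN+ replicate 2 it was 0.0553 for Mecom. Cdkn1c also lost its call without any one of EMCN- replicate 2 and EMCN+ replicates 1, 2 and 3 (adjusted p from 0.0537). The quiescence list had a camera adjusted p of 0.171 without EMCN- replicate 2 and 0.0546 without EMCN+ replicate 4.

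All 43 S phase genes had a negative change, with a median of -0.40, and 3 fell and 0 rose (22 and 0 adjusted over the list alone). The 3 genes were Ccne2 (-1.10 ± 0.19, edgeR adjusted p = 0.00402), Gmnn (-0.82 ± 0.16, adjusted p = 0.00881) and Tyms (-0.52 ± 0.13, adjusted p = 0.0418). Of 17 genes of G1 entry and early progenitors 6 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.39. Cdk6, a kinase of the entry into G1, fell from 200 ± 43.6 to 108 ± 17.9 CPM (edgeR adjusted p = 0.00217), and Nkg7 fell by 1.89 ± 0.29 (adjusted p = 0.00163). The 52 G2/M genes had a median of -0.23 and the 66 histone genes -0.81, with 0 called members in either list, also adjusted over the list alone. Ckap2 (-0.76 ± 0.23) and H4c1 (-0.98 ± 0.25) had the smallest p in these lists, with edgeR adjusted p of 0.107 and 0.0793. Of 27 alternatives Ckap2 passed in 4 and H4c1 in 8, with adjusted p of 0.0478 and 0.00708 with mouse as a block in the 6 libraries of complete pairs and 0.0267 and 0.00175 without EMCN+ replicate 1. With mouse as a block in all 11 libraries they had 0.131 and 0.156. Camera adjusted p values were 6.22e-15 for S phase, 7.53e-07 for G1 entry, 0.00173 for G2/M and 1.74e-18 for histones. In that order they were adjusted p = 0.214, 0.137, 0.628 and 0.357 with an estimated correlation. Histone copies are near identical, so the assignment of their reads is uncertain. Without EMCN- replicate 1 the adjusted p was 0.0647 for Ccne2, 0.084 for Gmnn and 0.379 for the G2/M list. That list also lost its call without EMCN+ replicate 3 (0.0585) or 4 (0.0893). Tyms had an adjusted p of 0.0533 with mouse as a block, and it lost its call without any one of 9 libraries, all but GMP replicates 1 and 2 (adjusted p from 0.0505 to 0.209).

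Of 87 cytosolic ribosomal protein genes 15 fell and 0 rose (59 and 0 adjusted over the list alone), 86 had a negative change and the median was -0.29. Rpl27 fell from 201 ± 18.3 to 121 ± 11.5 CPM (edgeR adjusted p = 0.00138) and Rpl35a from 295 ± 17.7 to 208 ± 3.18 CPM (adjusted p = 0.00881). Rpl35a was not called with scaling by total counts (adjusted p = 0.0968), and ribosomal protein genes can share reads with processed pseudogenes. Of 83 oxidative phosphorylation genes 24 fell and 0 rose (49 and 0 adjusted over the list alone), with a median of -0.45. Cox7c fell from 29.8 ± 8.48 to 15.2 ± 1.36 CPM (edgeR adjusted p = 0.00563) and Atp5mpl from 132 ± 15.6 to 79.5 ± 11.6 CPM (adjusted p = 0.00665). Without EMCN- replicate 1 the adjusted p of Cox7c and Atp5mpl was 0.0647. Of 13 mitochondrially encoded genes 2 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.32, namely mt-Nd2 (-0.47 ± 0.11, adjusted p = 0.0317) and mt-Nd1 (-0.43 ± 0.11, adjusted p = 0.05). Of 40 ribosome biogenesis genes Wdr12 fell (-0.45 ± 0.11, adjusted p = 0.0431) and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.26. The camera test gave adjusted p values of 1.3e-25 for ribosomal proteins, 1.3e-25 for oxidative phosphorylation, 5.66e-05 for mitochondrially encoded genes and 4.87e-09 for ribosome biogenesis. In that order they were adjusted p = 0.0883, 0.0796, 0.357 and 0.357 with an estimated correlation. Without a call were mt-Nd2 when any one of EMCN- replicates 1, 2 and 4 and EMCN+ replicates 2 and 3 was left out (adjusted p from 0.0575 to 0.173), and mt-Nd1 for 10 libraries, all but EMCN+ replicate 3 (0.0524 to 0.309). Wdr12 had no call without any one of 8 libraries, all but EMCN+ replicate 1, EMCN- replicate 2 and GMP replicate 1 (adjusted p from 0.0516 to 0.334). With scaling by total counts these adjusted p values were 0.186 for mt-Nd2, 0.238 for mt-Nd1 and 0.263 for Wdr12, while the medians of all these lists and of the cell cycle lists stayed negative.

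Of 27 megakaryocyte and platelet genes 4 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.15. Pf4, Itga2b and Plek were among those that fell, while Vwf, the von Willebrand factor gene of platelet-biased stem cells, rose to 129 ± 32.8 from 49.8 ± 4.42 CPM (edgeR adjusted p = 0.0168). The list had a camera adjusted p of 0.0433, and adjusted p = 0.374 with an estimated correlation. It had 0.0825 with mouse as a block, 0.278 without EMCN- replicate 1 and 0.171 without EMCN+ replicate 4. Vwf had an adjusted p of 0.0595 with mouse as a block, and from 0.0627 to 0.124 without any one of EMCN- replicates 1, 2 and 4. Of 45 adhesion and transmigration genes 4 fell and 0 rose (6 and 4 adjusted over the list alone), with a median of 0.01 and a camera adjusted p of 0.555. The GTPase gene Rap1b fell from 192 ± 44.1 to 127 ± 16.7 CPM (edgeR adjusted p = 0.0231). Of 15 lymphoid priming genes 2 rose and 0 fell, also adjusted over the list alone, namely Notch1 (0.71 ± 0.14, adjusted p = 0.0118) and Lsp1 (0.46 ± 0.11, adjusted p = 0.041). That list had a median of -0.04, a mean of 0.09 and a camera adjusted p of 0.503. Of 30 GMP genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 0.433. Gfi1 and the glutathione transferase gene Gstm1 (0.47 ± 0.12, edgeR adjusted p = 0.0463) rose, and Plac8 was among those that fell. With scaling by total counts Rap1b had an adjusted p of 0.141, and the medians of the lymphoid and GMP lists turned to 0.08 and 0.00132. Without any one of EMCN- replicates 1 and 4 and EMCN+ replicates 2 and 4 Rap1b had an adjusted p from 0.0587 to 0.251, and with EMCN+ replicate 3 added to these libraries Lsp1 had 0.0691 to 0.287. Notch1 had an adjusted p of 0.061 without EMCN- replicate 1 and 0.0627 without EMCN- replicate 2, and Gstm1 from 0.0506 to 0.180 without any one of 9 libraries, all but EMCN+ replicate 1 and GMP replicate 1.

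Of 20 endothelial markers 11 were tested. All 11 had a positive change, with a median of 0.41 and 0 called members, also adjusted over the list alone. Whether endothelial cells were present in the EMCN+ gate was not tested. Kdr stood at 8.11 ± 1.59 against 4.56 ± 0.402 CPM, Clec14a at 5.76 ± 0.789 against 2.23 ± 0.507, Tie1 at 83.6 ± 18.0 against 66.3 ± 4.06 and Egfl7 at 32.8 ± 3.65 against 27.4 ± 6.60. The list had a camera adjusted p of 9.3e-05, and adjusted p = 0.0883 with an estimated correlation. The 28 interferon response genes had a median of 0.14 and 0 called members, also adjusted over the list alone, and Stat2 stood at 36.7 ± 5.95 against 26.1 ± 4.90 CPM. The interferon list had a camera adjusted p of 0.0289, and adjusted p = 0.556 with an estimated correlation. It had 0.0607 with mouse as a block, 0.105 without EMCN- replicate 1, 0.457 without EMCN- replicate 4, 0.0961 without EMCN+ replicate 2 and 0.068 without EMCN+ replicate 3. Of 16 erythroid markers 2 fell and 0 rose, also adjusted over the list alone, with a median of -0.82. They were Aqp1 and the carbonic anhydrase gene Car1, which had 0 counts in EMCN+ and 13 in EMCN- libraries and was at least 9.82-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0387). Car1 was not tested in the fits of LT-HSC libraries alone, where its counts were below the filter. It had an adjusted p of 0.0568 with mouse as a block, and from 0.051 to 0.163 without any one of 9 libraries, all but EMCN- replicate 2 and GMP replicate 1. The erythroid list had a camera adjusted p of 0.0256, and adjusted p = 0.469 with an estimated correlation. It had 0.0533 without EMCN+ replicate 4 and 0.119 without EMCN- replicate 4.

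Further lists did not pass camera in this comparison. The camera adjusted p was 0.185 for 23 glycolysis genes (0 called, 2 higher and 2 lower adjusted over the list alone), 0.612 for 37 lysosome and autophagy genes and 0.682 for 25 immediate early genes (0 called, 1 higher adjusted over the list alone). It was 0.952 for 15 neutrophil and monocyte markers, 0.502 for 10 mast cell and basophil markers, 0.952 for 5 stromal markers and 0.952 for 21 antigen presentation genes, with 0 called members in each, also adjusted over the list alone. The median of the neutrophil and monocyte markers was 0.13, or 0.02 without 1 gene that had at most 3 counts in each fraction, and that of the mast cell markers was 0.00, or 1.05 without 5 such genes. Markers of B cells and of T and NK cells had 4 and 3 tested genes and no list test. They summed to 70.6 ± 8.09 and 13.3 ± 3.21 CPM in EMCN+ LT-HSCs, 55.8 ± 7.88 and 12.5 ± 1.18 CPM in EMCN- LT-HSCs and 176 ± 16.7 and 5.16 ± 1.01 CPM in GMPs. In all, 14 of 25 lists passed camera at the preset correlation, 4 higher and 10 lower, 7 passed fry and 0 passed camera with an estimated correlation.

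**Figure D2:**
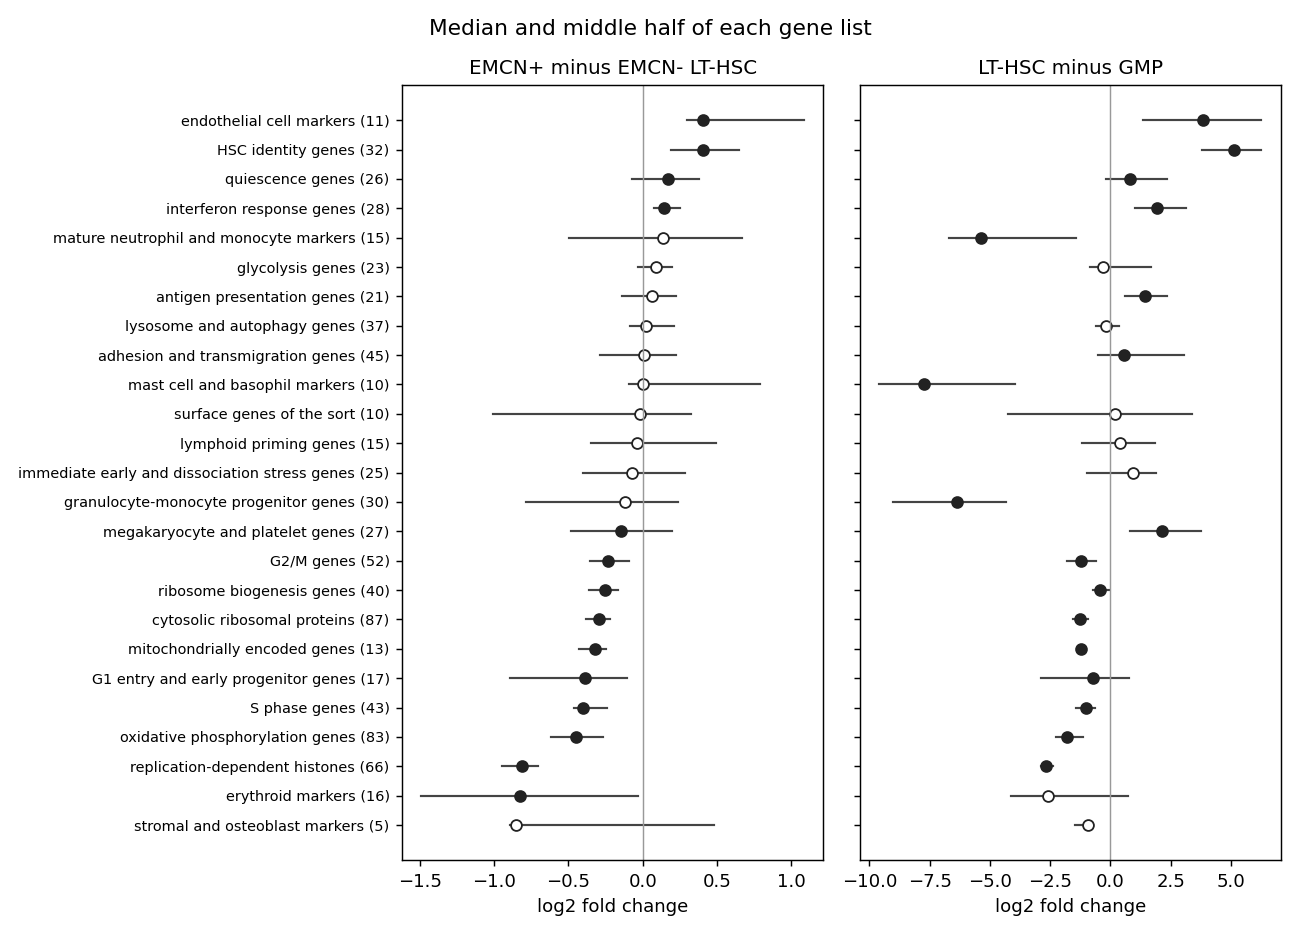
Points are the median log2 fold change of each gene list and lines its interquartile range, for EMCN+ versus EMCN- LT-HSCs and for LT-HSCs versus GMPs, and filled points passed camera at the preset correlation. Oxidative phosphorylation genes lie at -0.45 and -1.80 and stem cell identity genes at 0.41 and 5.11.

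The comparison of LT-HSCs with GMPs asked what separates the stem cells from a progenitor of granulocytes and monocytes. The myeloperoxidase gene Mpo (ENSMUSG00000009350.13, chromosome 11 from 87793581 to 87804413) stood at 11439 ± 1388 CPM in GMPs (SD, n = 4) and 2.21 ± 1.95 CPM in LT-HSCs (n = 7). The granule protease genes Elane and Prtn3 stood at 2629 ± 133 and 1320 ± 130 CPM in GMPs and at 0.356 ± 0.526 and 21.1 ± 3.29 CPM in LT-HSCs. The stem cell transcription factor genes Mycn and Mecom stood at 188 ± 28.1 and 224 ± 53.8 CPM in LT-HSCs and at 0.362 ± 0.139 and 1.58 ± 0.739 CPM in GMPs, and Hlf rose by 5.64 ± 0.13 (SE) on the log2 scale. Of 14915 genes tested, 9315 differed by the edgeR quasi-likelihood test, 4852 higher and 4463 lower in LT-HSCs, and 2925 and 2501 of them by more than 1 on the log2 scale. Scaling by total counts moved the median gene by 0.78 and gave 9063 higher and 1907 lower genes, and upper-quartile factors moved it by 0.12, so changes are relative to the median gene under TMM.

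The 10 genes named for their fitted increase had 0 counts in all 4 GMP libraries, so a bound is given against a floor of 3 counts over the group, and the bounds do not rank them above genes with counts in GMPs. The endothelial adhesion gene Esam, at 40.6 ± 5.76 CPM in LT-HSCs, was at least 312-fold higher. The bound was at least 236-fold for Nrk, 202-fold for Klhl4, 199-fold for Slc16a12, 174-fold for Evc2, 170-fold for Cdcp1, 169-fold for Sla2, 149-fold for Lurap1, 129-fold for the noncoding RNA Gimap1os and 125-fold for Fam110c. Their edgeR adjusted p values were 7.86e-10 (Slc16a12) or less. Clec5a, Gzmb and Dmkn had 0 counts in the 7 LT-HSC libraries and were at least 934-fold, 569-fold and 410-fold lower. The cathepsin G gene Ctsg had 2 counts against 28545, a ratio of 35649 with a 95% counting interval from 9868 to 294383. Log2 changes were -13.01 ± 0.42 for Elane, -12.78 ± 0.38 for Mpo, -12.70 ± 0.28 for Ly6c2, -11.12 ± 0.21 for Atp8b4, -11.10 ± 0.28 for Ms4a3 and -10.61 ± 0.35 for F13a1, with edgeR adjusted p of 3.53e-09 (Elane) or less. Among the surface genes of the sort, Emcn rose by 5.41 ± 0.37, Ly6a by 6.19 ± 0.48, Slamf1 by 3.95 ± 0.25, Kit by 1.62 ± 0.11 and Ptprc by 0.78 ± 0.09. Log2 changes were -8.39 ± 0.15 for Fcgr3 and -5.51 ± 0.39 for Fcgr2b, near-identical genes of the CD16 and CD32 proteins by which GMPs are gated, -5.34 ± 0.21 for Cd48, -0.90 ± 0.23 for Itgam and -0.42 ± 0.09 for Cd34. With scaling by total counts Cd34 turned to 0.36, and Itgam was not called (adjusted p = 0.699).

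All 32 stem cell identity genes rose, also adjusted over the list alone, with a median of 5.11, among them Mycn by 8.95 ± 0.21 and Fgd5 by 8.62 ± 0.28. The list had a camera adjusted p of 6.19e-17, and adjusted p = 0.00645 with an estimated correlation, a call it lost when mouse was a block as well (adjusted p = 0.0502). All 30 GMP genes fell, also adjusted over the list alone, with a median of -6.36, among them Igsf6 (-8.62 ± 0.15) and Prtn3 (-5.98 ± 0.12). Their camera adjusted p was 4.35e-19, and adjusted p = 0.00139 with an estimated correlation. At the preset correlation 18 of 25 lists passed, 7 higher and 11 lower, 22 passed fry, and only these 2 lists passed with an estimated correlation. Of 26 quiescence genes 16 rose and 6 fell, also adjusted over the list alone, with a median of 0.82 (camera adjusted p = 0.00656, and adjusted p = 0.063 with an estimated correlation). Txnip rose by 3.48 ± 0.12, and Cdkn1c had 1428 counts against 2, a ratio of 286 with a counting interval from 79.0 to 2363. Of 27 megakaryocyte and platelet genes 21 rose and 0 fell (21 and 1 adjusted over the list alone), with a median of 2.13 (camera adjusted p = 1.76e-06, and adjusted p = 0.0601 with an estimated correlation). They included the transcription factor genes Zfpm1 (3.87 ± 0.16) and Gfi1b (3.55 ± 0.20). Of 45 adhesion and transmigration genes 27 rose and 15 fell, also adjusted over the list alone, with a median of 0.56. Robo4, the gene of an endothelial guidance receptor, had 1836 counts against 2, a ratio of 368 with a counting interval from 102 to 3037. The adhesion list had a camera adjusted p of 0.04, and adjusted p = 0.23 with an estimated correlation. It had 0.0603 with mouse as a block and 0.0542 without EMCN- replicate 1.

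Genes of proliferation were lower in LT-HSCs, with list medians of -2.67 for histones (62 of 66 lower, 0 higher), -1.01 for S phase (40 of 43 lower, 1 higher), -1.23 for G2/M (43 of 52 lower, 2 higher) and -0.73 for G1 entry (12 of 17 lower, 5 higher). Adjusted over the list alone, S phase had 2 higher genes and the other counts were the same. Log2 changes were -2.99 ± 0.19 for H4c1, -2.88 ± 0.14 for the cyclin gene Ccne2, -2.64 ± 0.12 for the replication inhibitor gene Gmnn, -2.39 ± 0.15 for Cdca3, -2.35 ± 0.16 for Cks1b and -5.95 ± 0.16 for Nkg7, with edgeR adjusted p of 1.34e-08 (H4c1) or less. Camera adjusted p values were 1.1e-15 for histones, 3.68e-10 for S phase, 2.86e-08 for G2/M and 0.00694 for G1 entry. In that order they were adjusted p = 0.276, 0.219, 0.334 and 0.292 with an estimated correlation. Genes of biosynthesis were lower too, with medians of -1.80 for oxidative phosphorylation (78 of 83 lower, 0 higher), -1.24 for ribosomal proteins (81 of 87 lower, 0 higher), -1.22 for mitochondrially encoded genes (11 of 13 lower, 1 higher) and -0.43 for ribosome biogenesis (25 of 40 lower, 1 higher), with the same counts adjusted over the list alone. Log2 changes were -3.08 ± 0.10 for Cox7b, -3.37 ± 0.12 for Rps27l, -2.00 ± 0.08 for Rpl34, -1.85 ± 0.09 for mt-Nd1 and -1.41 ± 0.11 for Nip7, and Mrto4 fell from 53.9 ± 7.54 to 18.0 ± 4.06 CPM. The camera test gave adjusted p values of 1.41e-23 for oxidative phosphorylation, 5.01e-23 for ribosomal proteins, 7.02e-05 for mitochondrially encoded genes and 0.000256 for ribosome biogenesis. In that order they were adjusted p = 0.0601, 0.0757, 0.219 and 0.414 with an estimated correlation. With scaling by total counts the medians turned to 0.05 for G1 entry and 0.35 for ribosome biogenesis (camera adjusted p = 0.313), and the other 6 medians stayed negative.

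Of 28 interferon response genes 22 rose and 1 fell, with a median of 1.92, among them Ddx58 (2.83 ± 0.14) and Oasl2 (3.69 ± 0.17). Of 21 antigen presentation genes 18 rose and 2 fell, with a median of 1.43, among them H2-Q6 (2.84 ± 0.14), which shares reads with near-identical neighbours. Of 11 endothelial markers 8 rose and 1 fell, with a median of 3.83, among them the receptor gene Tie1 (3.66 ± 0.16). Camera adjusted p values of these 3 lists were 4.51e-07, 7.67e-05 and 0.000922, and adjusted p = 0.113, 0.0836 and 0.0836 with an estimated correlation. Of 15 neutrophil and monocyte markers 12 fell and 0 rose, with a median of -5.36, among them S100a8 (-9.12 ± 0.42) and the chemokine receptor gene Ccr2 (-8.32 ± 0.24). Of 10 mast cell and basophil markers 8 fell and 1 rose, with a median of -7.74, or -7.47 with genes at 0 counts set to their bound. Camera adjusted p values of these 2 lists were 0.000296 and 0.000116, and adjusted p = 0.113 and 0.0836 with an estimated correlation. The counts of these 5 lists were the same adjusted over the list alone.

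The camera adjusted p was 0.587 for 23 glycolysis genes (10 higher, 12 lower, and 11 and 12 adjusted over the list alone), 0.102 for 37 lysosome and autophagy genes (9 and 17), 0.342 for 15 lymphoid priming genes (8 and 5) and 0.161 for 16 erythroid markers (4 and 10). It was 0.564 for 5 stromal markers (1 and 1), 0.933 for 10 surface genes of the sort (5 and 5) and 0.266 for 25 immediate early genes (13 and 9), and apart from glycolysis the counts were the same adjusted over the list alone. Single members moved strongly in either direction. The glycolysis genes Hk3 and Pgam1 changed by -3.57 ± 0.11 and -2.59 ± 0.10, and the autophagy gene Gabarapl1 rose by 2.05 ± 0.12 and the leukocyte gene Lsp1 by 2.82 ± 0.11. The carbonic anhydrase gene Car2 rose to 438 ± 43.7 from 28.6 ± 8.82 CPM, the immediate early gene Egr1 rose by 5.64 ± 0.33 and Cebpb fell by 1.79 ± 0.14, with edgeR adjusted p of 1.1e-09 (Egr1) or less. The glycolysis list had a median of -0.30 and a mean of 0.33, and the surface list a median of 0.18 and a mean of -0.26. With scaling by total counts the median turned to 0.49 for glycolysis and 0.59 for lysosome and autophagy genes, from -0.19. Erythroid markers passed camera with total counts (adjusted p = 0.00083) and without EMCN- replicate 4 (0.0403).

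Each LT-HSC fraction was also compared with GMPs. Mecom rose by 7.34 ± 0.19 (SE) in EMCN+ and 6.70 ± 0.19 in EMCN- LT-HSCs, Emcn by 5.79 ± 0.38 and 4.92 ± 0.41, and Vwf by 6.52 ± 0.34 and 5.14 ± 0.36 on the log2 scale. Cd48 changed by -6.31 ± 0.28 and -4.05 ± 0.27 and Plac8 by -7.35 ± 0.24 and -5.61 ± 0.25 in the same order. Itga2b was called higher than in GMPs in EMCN- LT-HSCs (1.78 ± 0.27, edgeR adjusted p = 7.91e-05) and had no call in EMCN+ LT-HSCs (0.25 ± 0.26, adjusted p = 0.432). Runx3 and Cd34 were called lower in EMCN+ LT-HSCs (-1.74 ± 0.12, adjusted p = 1.33e-10, and -0.68 ± 0.11, adjusted p = 1.44e-05) and had no call in EMCN- LT-HSCs (-0.27 ± 0.13, adjusted p = 0.0895, and -0.07 ± 0.12, adjusted p = 0.638). The direct test of these 3 differences is the comparison of EMCN+ with EMCN- LT-HSCs, where all 3 genes fell. With scaling by total counts, which moved the median gene by 0.83 in EMCN+ and 0.72 in EMCN- LT-HSCs, Cd34 turned to 0.15 and 0.65 and Runx3 to 0.46 in EMCN- LT-HSCs, and Itga2b was called higher in EMCN+ LT-HSCs (1.07, adjusted p = 0.00613). Runx3 was called lower in EMCN- LT-HSCs without GMP replicate 4 (-0.33, adjusted p = 0.0463). The edgeR test called 9146 genes in EMCN+ LT-HSCs (4760 higher, 4386 lower) and 7859 in EMCN- LT-HSCs (4222 higher, 3637 lower). With total counts there were 8973 higher and 1877 lower genes in EMCN+ and 8209 and 1473 in EMCN- LT-HSCs. These comparisons share the GMP libraries and their chance values, and the second rests on 3 EMCN- libraries, so the counts were not set against each other.

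The position of both fractions between stem cell and progenitor expression was measured with 200 LT-HSC-high genes and 200 GMP-high genes, those with the smallest p in each direction of LT-HSCs versus GMPs. The sets were chosen from the same libraries, with weights that make that contrast independent of EMCN+ versus EMCN- under equal spread. In EMCN+ relative to EMCN- LT-HSCs the LT-HSC-high genes had a median of 0.31, with 30 higher, 0 lower and 179 of 200 positive. The GMP-high genes had a median of -0.38, with 3 higher and 64 lower. Camera adjusted p values were 1.71e-17 and 2.68e-22, and adjusted p = 0.0101 for both with an estimated correlation. The score of a library is its mean log2 CPM over the LT-HSC-high genes minus that over the GMP-high genes. It was 2.31 ± 0.12 (SD, n = 4) in EMCN+ and 1.69 ± 0.12 (n = 3) in EMCN- LT-HSCs and -5.31 ± 0.14 (n = 4) in GMPs. The difference of 0.62 between the fractions was 8.46% of the distance from LT-HSCs to GMPs and was positive in 3 of 3 within-mouse pairs, from 0.54 to 0.71. An exact two-sided permutation test gave p = 0.0286, the smallest that 35 splits allow, and these splits do not keep the mouse pairs. The sets were ranked by p values that use the spread within the real groups. They stayed the same over the splits, which may favour the real split. Across genes, which are not independent replicates, the log2 changes of both contrasts had a Pearson correlation of 0.308 and a Spearman correlation of 0.443. Means were -0.0247 and -0.00768 in 20 simulations that kept the LT-HSC versus GMP difference but had none between the EMCN fractions. Genes were drawn independently there, so the simulations do not show how far these correlations vary in real libraries. Without EMCN- replicate 1 there were 4 higher LT-HSC-high and 11 lower GMP-high genes, without EMCN+ replicate 2 there were 9 and 24, without EMCN- replicate 4 there were 16 and 49, without EMCN+ replicate 4 there were 21 and 37, and with mice 2 to 4 there were 5 and 26. The medians were 0.42 and -0.25 with scaling by total counts, with 42 higher LT-HSC-high genes and 4 higher and 20 lower GMP-high genes.

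**Figure D3:**
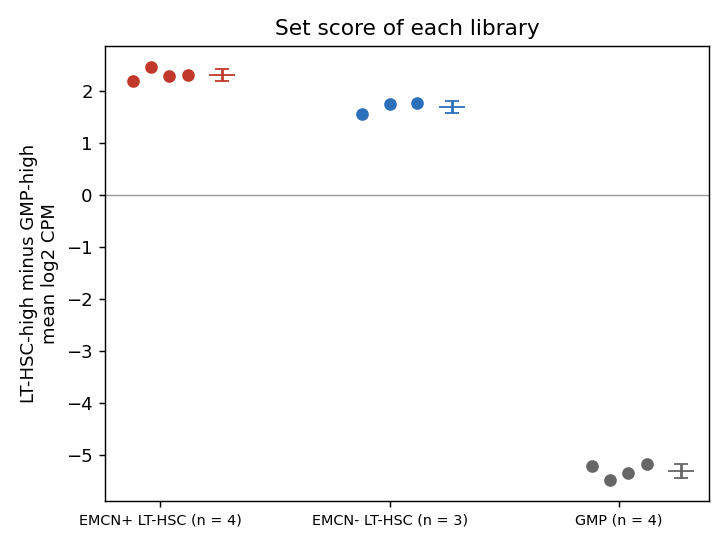
Points are libraries and bars the group mean with SD of the score, the mean log2 CPM of LT-HSC-high genes minus that of GMP-high genes, for EMCN+ LT-HSCs (4 libraries), EMCN- LT-HSCs (3) and GMPs (4). All EMCN+ libraries lie at 2.19 or above and all EMCN- libraries at 1.76 or below, far from the GMP mean of -5.31.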

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

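The tests of GMP cells and of other progenitors in the EMCN- gate were chosen after the results were seen, and the thinning of libraries and the length and GC correction were tests added after the data were seen.

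Genes high in GMPs were higher in EMCN- than in EMCN+ LT-HSCs, with a median log2 change of -0.38 over 200 genes, 64 of them called lower in EMCN+. The median was -0.249 with scaling by total counts, with 20 called lower. The tables argue against GMP cells in the EMCN- gate as the cause, since Mpo, Elane, Plac8, Ctsg and Prtn3 together show a share of GMP RNA of at most 0.204% in an EMCN- library, where 5.28% would be needed. They also argue against lower depth, since the median was -0.392 with every library thinned to the smallest total. Progenitors other than GMPs cannot be told apart from a shift within the stem cells, since Cd48 was higher in EMCN- libraries by 4.64% of its GMP level and Plac8 by 1.44%, no library of such progenitors sets a bound, and the CD48 gate is meant to remove such cells. A difference of the EMCN fractions with the animal held constant is consistent with a median of -0.393 with mouse as a block.

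Oxidative phosphorylation genes had a median of -0.45 and ribosomal protein genes -0.29 in EMCN+ relative to EMCN- LT-HSCs, and both kinds of transcript are short. Length and GC content as the whole cause is argued against by 1000 lists of other genes matched on length, GC content and expression, whose lowest medians were -0.168 and -0.261, with bootstrap SDs of the lists' own medians of 0.0376 and 0.0135. For the ribosomal proteins the matched lists had a median of -0.155, so that part of the change may go with length and GC content. For each list only its own members were kept out of the matching, so genes of the other lists that fell could be drawn. The matched lists therefore cannot separate length and GC content from a fall shared with such genes. A correction for both in the 7 LT-HSC libraries moved the median from -0.457 to -0.381 and the called genes from 13 to 7 for oxidative phosphorylation, and from -0.309 to -0.239 and 13 to 5 for ribosomal proteins. A lower output of these genes in EMCN+ LT-HSCs stays open as a hypothesis, as do reads shared with pseudogenes, which were not tested.

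For the 293 genes of EMCN+ versus EMCN- LT-HSCs, 1 of 35 splits of the 7 libraries, the real one, gave as many. This share is under 0.05, and the highest other split gave 76 genes, but these splits do not keep the mouse pairs. Among the 8 splits that part all 3 mouse pairs, as the real one does, the highest other gave 2 genes, and the split with 76 parts 2 pairs. For the 14 gene lists 1 of 35 splits, the real one, gave as many (highest other 12, or 10 among the splits that part all pairs). The split that passed 12 lists had 0 called genes, so the number of lists sets the real split little apart. For the set difference of 0.687 it was 1 of 35 splits (highest other 0.595, or 0.552 among the splits that part all pairs). The sets were ranked with the spread within the real groups and stayed the same over the splits, which may favour the real split. The 8 splits that part all pairs are too few for a share under 0.05. With the pairs kept, chance is therefore not excluded for these genes, lists and set difference. Against GMPs only the real split gave as many as the 9315 genes of LT-HSCs (1 of 100 splits drawn, highest other 1). The same held for the 9146 genes of EMCN+ LT-HSCs (1 of 35, highest other 0) and the 7859 genes of EMCN- LT-HSCs (1 of 35). These shares are under 0.05, over splits that do not keep the mice either. For EMCN- LT-HSCs versus GMPs the highest other split gave 2702 genes, with 3 GMP libraries in one group, which points to the structure of the samples. For the 18 lists of LT-HSCs versus GMPs 3 of 100 splits gave as many, the real one included, and the highest other gave 18, so the number of lists does not set the real split apart.

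The EMCN+ LT-HSC and GMP groups were searched for a library far from the other 3 of its group. The EMCN- libraries were not searched, although leaving out EMCN- replicate 1 lowered the number of called genes most, from 293 to 55. Of 185 tests 9 (4.86%) were flagged, where chance gives about 1 in 20 groups. Of the 9 flags 5 were in EMCN+ replicate 2. There Vwf was at 178 CPM against 110 to 117 CPM, Notch1 at 90.2 against 58.6 to 63.8 CPM and Fgd5 at 138 against 108 to 112 CPM. In the same library Atp8b4 was at 0.139 CPM (2 counts) and Ms4a3 at 0.349 CPM (5 counts), against 0 in the others. With 0 in the others any count is flagged, so these flags may be counting noise. Atp5mpl was at 96.7 CPM in EMCN+ replicate 1 against 72.5 to 75.4 CPM. Pgam1 was at 62.8 CPM in EMCN+ replicate 3 against 44.7 to 46.8 CPM, and at 272 CPM in GMP replicate 4 against 300 to 304 CPM. Ms4a3 was at 386 CPM in GMP replicate 3 against 410 to 413 CPM.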

How the results depend on the processing

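Total-count scaling, protein-coding genes alone, mice 2 to 4, the length and GC correction, thinning and the estimated correlation with a mouse block were tests chosen after the data were seen. Of 45 named genes called in EMCN+ versus EMCN- LT-HSCs, 15 were called in every alternative that gave a value: H19, Pdgfc, Ndnf, Igf1, Sult1a1, Smtnl1, Ncam2, Pf4, Plac8, Spns3, Runx3, Dnajc6, Mllt3, Gfi1 and Rpl27. Of 66 called in LT-HSCs versus GMPs 64 were, all but Cd34 and Itgam under total counts, and 6 of 7 in EMCN+ and 6 of 6 in EMCN- LT-HSCs versus GMPs. The score of the 2 gene sets separated the fractions in every alternative in which it was computed, with differences from 0.544 to 0.722. The number of genes in EMCN+ versus EMCN- LT-HSCs was 529 (236 higher, 293 lower) without a low-count filter, 451 (203 higher) with DESeq2, 464 (187 higher, 277 lower) with protein-coding genes alone and 90 (35 higher, 55 lower) with mice 2 to 4, where fewer libraries were fitted. It was 908 (380 higher, 528 lower) with the 6 libraries of complete pairs and mouse as a block, and 969 (389 higher, 580 lower) with the length and GC correction and mouse as a block. Against 115 higher and 178 lower genes in the main fit, there were 88 and 117 without robust dispersion and 161 and 50 with total counts. With the 7 LT-HSC libraries there were 151 and 118, or 154 and 123 with the length and GC correction and no mouse block. With limma-voom there were 129 and 125. The majority was thus higher rather than lower with total counts, with limma-voom and, without a mouse block, with the 7 LT-HSC libraries, corrected or not. Leaving out each library in turn gave 55 to 338 genes, 26 to 123 higher and 29 to 221 lower. With total counts there were 9063 higher and 1907 lower genes in LT-HSCs versus GMPs, 8973 and 1877 in EMCN+ and 8209 and 1473 in EMCN- LT-HSCs versus GMPs, since that scaling shifts the median gene.

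With an estimated correlation 0 lists passed in EMCN+ versus EMCN- LT-HSCs (0 higher, 0 lower) and 2 in LT-HSCs versus GMPs (1 higher, 1 lower). With an estimated correlation and mouse as a block there were 0 (0 higher, 0 lower) and 1 (0 higher, 1 lower). The list lost there was that of stem cell identity genes (adjusted p = 0.0502). In the fit of all 11 libraries mouse as a block ended no call named in the report beyond those given with it there. Kit turned to -0.00455 with the 7 LT-HSC libraries, -0.0433 with the length and GC correction, -0.00886 with that correction and mouse as a block and -0.00559 when thinned, and ran from -0.0748 to 0.0953 with each library left out. Ptprc turned to 0.0689 with total counts and ran from -0.0990 to 0.0516 with each library left out. Cd34 versus GMPs turned to 0.36 in LT-HSCs, 0.15 in EMCN+ and 0.65 in EMCN- LT-HSCs with total counts, and to 0.0397 in EMCN- LT-HSCs with upper-quartile factors, and Runx3 to 0.46 in EMCN- LT-HSCs with total counts. The direction of camera, which compares a list with other genes, turned for some lists without a call, whose mean changes were then as follows. In EMCN+ versus EMCN- LT-HSCs these were neutrophil and monocyte markers (0.267 with RLE, 0.191 with mouse as a block under either correlation, 0.373 with total counts, -0.115 with the length and GC correction, -0.317 when thinned), mast cell markers (0.0818 when thinned), stromal markers (0.295 with mice 2 to 4), antigen presentation genes (0.0369 with mouse as a block) and immediate early genes (-0.0244 with mouse as a block). With each LT-HSC library left out the means ran from -0.0626 to 0.726 for neutrophil and monocyte markers, -0.186 to 0.271 for stromal markers, 0.000794 to 0.111 for antigen presentation genes and -0.230 to -0.0266 for immediate early genes. In LT-HSCs versus GMPs the direction turned for surface genes (-0.271 with mouse as a block, 0.514 with total counts, -0.345 with mice 2 to 4) and erythroid markers (-0.592 with the filter at 5 CPM). The cause of these changes was not tested. Thinning and the filter at 5 CPM gave no value for Car1 and the stromal list, the fits of LT-HSC libraries alone none for Car1 and Fcgr3, the length and GC correction none for the stromal and mast cell lists, leaving out EMCN+ replicate 1, 2 or 3 none for the stromal list, and protein-coding genes alone none for H19, Meg3, Rian and Gimap1os. Among called lists of EMCN+ versus EMCN- LT-HSCs, megakaryocyte genes had a camera adjusted p of 0.251 with the filter at 5 CPM, 0.0516 with protein-coding genes, 0.203 with mice 2 to 4 and 0.0721 when thinned. Erythroid markers had 0.537 with that filter, 0.146 with the length and GC correction and 0.222 when thinned, interferon genes 0.140 with mice 2 to 4 and 0.0623 when thinned, and quiescence genes 0.143 with the length and GC correction, where glycolysis passed with 0.0389. In LT-HSCs versus GMPs adhesion genes had 0.072 with protein-coding genes. Over 27 alternatives the edgeR, DESeq2 or limma adjusted p ran from 9.86e-05 to 0.275 for Aqp1, 0.0218 to 0.209 for Tyms, 1.61e-16 to 0.131 for Vwf, 5.81e-05 to 0.0912 for Cd34, 5.47e-06 to 0.0968 for Rpl35a, 0.00267 to 0.186 for mt-Nd2, 0.00745 to 0.410 for mt-Nd1, 0.00901 to 0.334 for Wdr12, 7.97e-05 to 0.323 for Rap1b, 0.00946 to 0.287 for Lsp1, 0.0128 to 0.180 for Gstm1 and 7.65e-05 to 0.0627 for Notch1. It ran from 8.66e-08 to 0.165 for Meg3 and Rian over 26 alternatives, from 0.000506 to 0.207 for Car1 over 21, and for Itgam in LT-HSCs versus GMPs from 5.55e-07 to 0.699 over 24. Mice 2 to 4 ended the calls of Procr (0.0531), Mecom (0.0893), Cdkn1c (0.273), Gmnn (0.064), Cox7c (0.0558) and Cdk6 (0.0536), the last in no other alternative. Nkg7 lost its call only with the 7 LT-HSC libraries (0.0657) and with these and the length and GC correction (0.0628), and Cyp26b1 only with limma-voom (0.059). Genes called in 1 alternative alone were Ly6a (0.0419) and Stat2 (0.0457) with the length and GC correction and mouse as a block, and Clec14a (0.0453) with the 6 libraries of complete pairs and mouse as a block. Every alternative named was run, but not for every result. The list and set tests and the score were not run with upper-quartile factors, no low-count filter, DESeq2, limma-voom or no robust dispersion. Nor were they run with the unweighted mean, a GMP library left out, or the uncorrected fits of the 7 LT-HSC libraries and of the 6 libraries of complete pairs. In simulated data at this depth changes of 1.5-fold were mostly not detected in genes with a mean of at least 5 CPM, the only ones changed.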

Other observations

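The test of other imprinted genes was chosen after the result was seen.

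H19, Meg3, Rian and Cdkn1c, the 4 named genes that are imprinted, were higher in EMCN+ than in EMCN- LT-HSCs. Of 40 other imprinted genes 27 were tested, with 19 positive and a median log2 change of 0.302. The called ones were the growth factor gene Igf2 (2.89 ± 0.51, edgeR adjusted p = 0.00706) and its receptor gene Igf2r (0.91 ± 0.18, adjusted p = 0.0134), both named after their values were seen. Camera on this 1 set gave p = 7.51e-06, and p = 0.00715 with an estimated correlation, in a model over all genes. Over 19 genes outside the 2 loci of the 4 genes the median was 0.33, with camera p = 0.0309 with an estimated correlation and 0.0917 when mouse was a block as well. With mouse as a block the median was 0.201 over the 27 genes and over the 19 genes. With every library thinned to the smallest total 21 genes were tested, with 14 positive and a median of 0.217. Camera then gave p = 0.0421 with an estimated correlation. Some large changes rest on few counts. Mirg, Zdbf2, Asb4, Dlk1 and Peg3 stood at 0.132, 0.396, 0.574, 0.784 and 0.872 CPM in EMCN- LT-HSCs, where 3 counts in a library were worth 0.459 to 0.705 CPM. A wider rise of imprinted genes in EMCN+ LT-HSCs may account for the 4 genes, as a hypothesis from the same libraries.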
